A study of Homo sapiens with 3 samples.

How the data were processed

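RNA was measured in 3 libraries of MDA-MB-231 tumorspheres, 1 each for untreated spheres, spheres with LINC00273 overexpression and spheres treated with 10 µM M2, after 24 h. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was removed with the RiboCop kit, and 150-bp paired-end reads were made on an Illumina HiSeq instrument. Per the submitters' processing notes, the tools were Trimmomatic, Bowtie2 2.2.4, STAR, featureCounts 1.5.2 and DESeq2, on the hg19 build. Their roles, order and settings, the annotation, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. An rRNA-depleted total RNA library keeps abundant non-coding RNAs such as RN7SL1 and RN7SK, whose share sets how many reads remain for other genes.

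The deposited tables give a signal per gene and library for 57773 genes, 1 table for each comparison with the control, and the control values were the same in both. The values were not whole, but within each library they were whole multiples of 1 step, which is the form of read counts divided by 1 size factor per library. Dividing by the step gave whole reads for 100% of the values within a tolerance of 0.01. The planned design had assumed counts, and the recovered reads were used in their place. Of genes with fewer than 20 reads, 82.3% (control), 80.5% (labelled LINC00273 overexpression) and 85.8% (M2) had an even number, so that most fragments were counted as 2 reads. Counting intervals and floors were therefore computed on fragments, which is reads divided by 2. The libraries hold 4310267, 2561600 and 2347768 such fragments. The ratio and log2 ratio columns deposited by the authors compare these scaled values. The authors' deposited term tables give a fold enrichment, a p-value and a false discovery rate per term, and are quoted as deposited.

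Recovered reads were scaled by TMM (edgeR 4.0.16, R 4.3.3), which gave effective library sizes of 7208511, 6139145 and 4686051. The log2 ratio of scaled reads was taken per gene without a prior, with a 95% exact binomial (Clopper-Pearson) interval of the split between libraries. With 1 library per group there are no residual degrees of freedom, so neither edgeR nor DESeq2 was used to test genes, and the number of genes called by a count test is not given. Instead a size rule was applied: at least 100 reads in 1 or both libraries and at least a 2-fold difference. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A gene with 0 reads in one library has a bound computed against 3 fragments in that library, and list medians take such genes at that bound.

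36 gene lists were fixed before the data were examined: EMT and mesenchymal genes, epithelial genes, matrix proteases and invasion genes, stemness factors, breast cancer stem cell markers, drug efflux and drug response genes, miR-200 family targets, promoter G-quadruplex oncogenes, the Notch pathway, Wnt targets and components, TGF-beta targets, YAP/TAZ targets, p53 targets, DNA repair and replication stress genes, BCL2 family and apoptosis genes, G1/S genes, G2/M genes, replication-dependent histones, interferon-stimulated genes, NF-kB cytokines and chemokines, ATF4 and unfolded protein response genes, heat shock genes, cholesterol biosynthesis and SREBP2 targets, hypoxia and glycolysis genes, NRF2 targets, immediate early genes, collagens and matrix, cytosolic ribosomal proteins, 7SL, 7SK and rRNA-like RNAs, nuclear long non-coding RNAs, metallothioneins, mitochondrially encoded genes, and markers of luminal breast, blood, fibroblast and HEK293-type and neural cells. A member was measured with at least 20 reads over the libraries compared, and a list needed 3 measured members. The median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, and members at least 1.5-fold higher or lower were counted. The percentile describes these libraries and is no test. The named genes were also chosen by a fixed rule: LINC00273, the 10 highest and 10 lowest protein-coding genes and the 3 highest and 3 lowest other genes per comparison, up to 4 members of each list with the largest ratios past 1.5-fold, and the first 4 members of the lists that the series title concerns. Further members named for comparison were chosen after their values were seen. Some genes that the rule names are not reported here.

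The alternatives planned were DESeq2 size factors (DESeq2 1.42.0), scaling to the total count, read minimums of 20 and 500 or none, protein-coding genes only, a 4-fold threshold (log2 of 2), a prior of 5 reads, random lists of protein-coding genes, and a random split of the control reads. The size factors of the deposited values and ratios centred on genes of like GC content were added after seeing the data. GC content, gene length, the position of LINC00273 and the number of pseudogenes came from GENCODE 29 on GRCh38, matched by Ensembl identifier, and no coordinate of the authors' build was used. GC content and gene length are those of the longest annotated transcript of each gene. At least 98.9% of the genes tested in each comparison had a GC content.

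The ratio step was tested on simulated libraries with 200 genes changed by a known fold. For the library labelled LINC00273 overexpression against the control (3709 and 3720 genes) the intervals held the true ratio for 95.7% of genes in the 2-fold and 95.2% in the 4-fold simulation, and for M2 against the control (3725 and 3745 genes) for 96.0% and 95.2%. The sign was right for 100% of the changed genes. For the relation between both comparisons, unchanged libraries were simulated 20 times at each noise level against the shared control. Genes past the bounds of the authors' lists were counted in 20 further simulations with counting noise only.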

Results

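The RNA of MDA-MB-231 tumorspheres was profiled in 3 libraries, 1 per group. MDA-MB-231 is an established human triple-negative breast cancer line, and tumorspheres are clusters that such cells form when they cannot attach, a culture used to enrich for stem-like cells. One library came from untreated spheres, one from spheres labelled as overexpressing the long non-coding RNA LINC00273, and one from spheres treated with 10 µM M2, a compound known here only by that code. Treatment lasted 24 h. The series title ties a G-quadruplex in LINC00273 to microRNA binding, metastasis, stemness and drug resistance, and the labels describe the tumour phenotype as more metastatic with LINC00273 and as regressing with M2. The libraries held 8620534 reads on genes (control), 5123199 (labelled LINC00273 overexpression) and 4695535 (M2). RN7SL1, the RNA of the signal recognition particle, and RN7SK, a regulator of transcription elongation, took 54.7%, 42.8% and 39.3% of these reads. At least 100 reads fell on 3665, 3310 and 3050 genes, respectively. With 1 library per group no difference has a replicate check, no p-value is given, and the ratios compare libraries rather than conditions. Intervals are 95% exact binomial (Clopper-Pearson) intervals of the read split and cover counting error only.

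LINC00273 (ENSG00000256642), the transcript named by the overexpression label, had 0 reads in all 3 libraries. In the GRCh38 annotation used here it is a single exon of 1452 nt on the minus strand of chromosome 16 (34158585 to 34160036), with a GC content of 70.4%. The median GC content of expressed genes was 45.8%, and 3 of 3831 reached that of LINC00273. A count of 0 allows up to 0.696 CPM in the control, 1.17 in the library labelled LINC00273 overexpression and 1.28 in the M2 library. These limits hold only if reads of this locus could be counted, which the sources used here do not settle. The overexpression was not seen in these counts, and every direction given for that library rests on its label alone.

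The first comparison asks which transcripts differ with LINC00273 overexpression. The library labelled LINC00273 overexpression had 7.73-fold more SMAD7, the inhibitory SMAD induced by TGF-beta signalling, than the control (315 against 2074 reads, log2 ratio 2.95, interval 2.71 to 3.20). SKIL, a repressor of SMAD-driven transcription, was 6.40-fold higher (log2 2.68, 1.69 to 3.82), whereas SMAD3, which carries the TGF-beta signal to the nucleus, was lower at −1.85 (−2.67 to −1.11). FLRT2, a cell-surface adhesion and guidance protein, was 6.63-fold higher and HAS2, which makes hyaluronan, was 4.55-fold higher. The globin gene HBB was 460-fold lower, with 4860 reads in the control and 9 in that library, and B2M, the light chain of MHC class I, had 119 and 0 reads.

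By size, 199 of 3842 genes with at least 100 reads in 1 or both libraries were at least 2-fold higher in the library labelled LINC00273 overexpression and 254 were at least 2-fold lower. The median log2 ratio of the tested genes was −0.21, so the 2-fold bounds were not centred on it. The counting interval of each gene past 2-fold lay beyond 0, which the read minimum and the 2-fold rule already ensure at these depths, so it is no further check. After SMAD7, FLRT2, SKIL and HAS2, the highest protein-coding genes were ASXL2, a chromatin regulator (log2 2.13, 1.74 to 2.53), GLCE, an enzyme of heparan sulfate synthesis (2.01, 1.34 to 2.73), and UGCG, which makes glucosylceramide (1.90). TMEFF2 (1.84, 1.51 to 2.17), FRS2, an adaptor of FGF receptors (1.80), and the collagen lysyl hydroxylase PLOD2 (1.79, 1.30 to 2.30) completed the 10. At the low end, HBA2 had 788 reads in the control and 0 in that library, at least 112-fold lower, and B2M was at least 16.9-fold lower. HBA1 had 168 reads in the control and 2 in that library, a log2 ratio of −6.16 (−11.48 to −3.64), and HBB stood at −8.85 (−10.58 to −7.56). TINAGL1 (−2.05), the purine synthesis enzyme ADSL (−2.04), the interferon-responsive factor IRF1 (−2.04, −2.98 to −1.19), TTC39C (−2.03, −2.36 to −1.73) and ZNF18 (−1.85) were also among the lowest. Among other genes, RP11-613H2.2 (1.46) and the pseudogenes TWF1P1 (1.34) and HSPD1P7 (0.95) were highest. RMRP, the RNA of RNase MRP, was lowest (−2.50, −3.78 to −1.41), followed by CTD-2328D6.1 (−1.89). Reads of pseudogenes and of their parent genes may have been split between them by the counting.

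The ratio moved with base composition and gene length. Across genes its rank correlation with GC content was −0.60, and the median log2 ratio was 0.45 in the fifth of genes with the lowest GC content and −0.62 in the fifth with the highest. The rank correlation with gene length, taken from the longest annotated transcript, was 0.43, and 0.32 given GC content. With ratios centred on genes of like GC content, 138 genes were higher and 134 lower, of which 87 and 68 were also past the threshold before. SMAD7 then stood at 3.56, SKIL at 2.23 and SMAD3 at −1.39. 10 of the 10 highest and 8 of the 10 lowest protein-coding genes and 1 of the 3 highest other genes stayed past 2-fold. The remaining lowest genes, B2M and HBA2, had 0 reads in the library labelled LINC00273 overexpression and so no centred value. Scaling to the total count moved the median of all genes by 0.52 and gave 823 higher and 37 lower genes (95.7% higher, against 43.9%), and the size factors of the deposited values gave 265 and 187 (58.6%).

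Genes of DNA repair and replication stress were the list that stood highest in the library labelled LINC00273 overexpression, with a median log2 ratio of 0.71 over 22 measured members. 13 members were at least 1.5-fold higher and 1 was lower, and the median exceeded that of 99.96% of matched random lists. No list in either comparison was matched or centred on gene length, with which the ratio also rose. CHEK1, a checkpoint kinase, had 10 and 36 reads (2.08, 0.60 to 3.86), and the helicases BLM (1.23, 0.29 to 2.23), DHX36 (1.14, 0.49 to 1.81) and DHX9 (1.04) were also higher. DHX36 unwinds G-quadruplexes. Targets of the miR-200 family, microRNAs that repress ZEB1 and ZEB2, had a median of 0.49 over 20 members, at percentile 99.8. 9 of the 20 were at least 1.5-fold higher and 0 lower. SUZ12 stood at 1.40 (1.11 to 1.69), FN1 at 1.45 (1.15 to 1.76), KLF9 at 0.96, ZEB1 at 0.94 (0.61 to 1.27), ZEB2 at 0.80 (0.69 to 0.91) and BMI1 at 0.53. Heat shock genes had a median of 0.50 (percentile 99.1, 6 of 12 higher, 0 lower), led by HSPA4L at 1.93, and lay at percentile 94.2 with no minimum. Oncogenes with promoter G-quadruplexes had a median of 0.44 (percentile 98.1), with 9 of 19 higher and 2 lower, but with a minimum of 100 reads it stood at 0.21 (percentile 89.2, 3 of 10 higher, 2 lower), inside the central 95% of random lists. VEGFA was higher (1.21, 0.97 to 1.45), RB1, a tumour suppressor that this list also holds, had 9 and 34 reads, and MYC stood at −0.23 (−0.64 to 0.18).

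6 lists lay below the central 95% of random lists. Of the 28 measured ribosomal protein genes, 19 were at least 1.5-fold lower and 0 higher (median −0.71, percentile 0.02), RPS14 among them at −1.08; control reads on this list ran from 14 (RPL30) to 42633 (RPLP0). The 7SL, 7SK and rRNA-like RNAs had a median of −1.04 (percentile 0.02, 9 of 10 lower), with RN7SK at −1.20. Hypoxia and glycolysis genes had a median of −0.68 (percentile 1.14, 8 of 15 lower, 2 higher): PFKFB3 stood at −1.68, the glucose transporter SLC2A1 at −1.08 and GAPDH at −0.96, while VEGFA, also on this list, was higher. With no minimum this list lay at percentile 24.0. Replication-dependent histones had a median of −0.76 (percentile 1.86, 5 of 8 lower), with HIST1H2BK at −0.96, and lay at percentile 6.40 with a minimum of 100 reads. NF-kB cytokines and chemokines had a median of −0.93 (percentile 2.15, 4 of 6 lower), and BIRC3 had 20 reads in the control and 0 in that library. This list moved inside the central 95% with DESeq2 size factors (percentile 2.5) and with scaling to the total count (−0.41, percentile 12.5). Blood cell markers, a list for cells that a tumorsphere culture should not hold, had a median of −6.16 (percentile 0) with 4 of 5 lower. The globins HBB, HBA1 and HBA2 were among the 5, and the median is the ratio of HBA1. The leukocyte genes of the 5 were split. PTPRC, the pan-leukocyte gene, had 38 reads in the control and 10 in that library, whereas ITGB2 had 10 and 15. With GC centring, 7 of these 10 lists stayed outside the central 95%. The ribosomal proteins, the hypoxia genes and the histones did not.

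The lists that the series title points to were mixed. Of 15 measured EMT and mesenchymal genes, 5 were higher and 3 lower, with a median of −0.17 (percentile 47.4) and a mean of 0.15. CDH2, N-cadherin, was higher (1.68, 1.17 to 2.22), and the EMT factor TWIST1 was lower (−1.04, −1.22 to −0.86). SNAI1 had 2, 0 and 0 reads in the control, the library labelled LINC00273 overexpression and the M2 library, SNAI2 had 16, 12 and 17, and TWIST2 stood at −0.61. Matrix proteases and invasion genes had a median of −0.67 (percentile 3.22, 4 of 7 lower, 1 higher). The sheddase ADAM10 was higher at 1.37 (1.14 to 1.61), and the protease inhibitor TIMP2 was lower at −1.30 (−1.62 to −0.99). Stemness factors had a median of −0.05 (percentile 55.4), and 11 of 12 lay within 1.5-fold of the control. SOX2 stood at −0.52 (−0.96 to −0.08) and ID3 at −1.04, KLF4 had 64 and 43 reads, and NANOG and POU5F1 had at most 4 reads in any library. Of the breast cancer stem cell markers 4 were measured, with a median of −0.09 (percentile 38.2). CD44 stood at −0.74 (−1.55 to 0.04), and PROM1 (16, 14 and 6 reads) and ALDH1A1 (2, 7 and 2) were too low for a difference to be detectable at this depth. Drug efflux and drug response genes had a median of 0.18 (percentile 84.5, 5 of 15 higher, 2 lower), with XIAP at 1.02 (0.66 to 1.40), TOP1 at 0.90 and BCL2L1 at −0.84. The efflux pumps ABCB1 (31 and 37 reads) and ABCC1 (16 and 22) did not differ beyond counting error. Epithelial genes had a median of 0.23 over 5 measured members (percentile 65.9), with the tight junction gene TJP1 at 1.26 (1.08 to 1.44).

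TGF-beta targets had a median of 0.37 (percentile 95.4), with 6 of 15 higher and 3 lower. Besides SMAD7 and SKIL, the receptor TGFBR1 (1.91, 0.98 to 2.93) and CTGF (1.53, 0.63 to 2.51) were higher, and BHLHE40 had 0 reads in the control and 24 in the library labelled LINC00273 overexpression. After GC centring the median of this list was 0.90, above 99.97% of random lists. YAP/TAZ targets had a median of 0.33 (percentile 93.9, 6 of 14 higher), with CYR61 at 1.33 (0.89 to 1.79) and CRIM1 at 1.30. The Notch pathway had a median of 0.41 (percentile 95.7), and RBPJ, its DNA-binding factor, stood at 1.22 (1.14 to 1.31) and its ligand JAG2 at −0.76. Wnt targets and components (−0.14, percentile 48.1), p53 targets (−0.08, 53.5), BCL2 family and apoptosis genes (−0.17, 42.2), G1/S genes (−0.08, 48.1) and G2/M genes (0.19, 84.0) lay within the central 95%. Among their members GADD45A stood at −1.29, PCNA at 1.59 and CDC20 at −1.22. The medians were −0.41 for ATF4 and unfolded protein response genes (percentile 7.53, DDIT3 at −1.92), −0.38 for NRF2 targets (12.2, GCLM at −0.96) and −0.43 for immediate early genes (6.29, DUSP6 at −1.49). Interferon-stimulated genes had 0.59 (84.9), cholesterol biosynthesis and SREBP2 targets 0.25 (80.9, INSIG1 at 1.40), and collagens and matrix −0.05 (45.4), with THBS1 at −1.12 (−1.19 to −1.06). Nuclear long non-coding RNAs had −0.22 (38.1): MALAT1 stood at −0.64, and NEAT1 had 36 reads in the control and 2 in that library. The markers of other cell types were luminal breast genes (0.17, 68.5), fibroblast genes (0.11, 53.7) and HEK293-type and neural genes (0.22, 64.3). 0 of 9 metallothioneins and 0 of 13 mitochondrially encoded genes reached the minimum of 20 reads in either comparison.

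**Figure D1:**
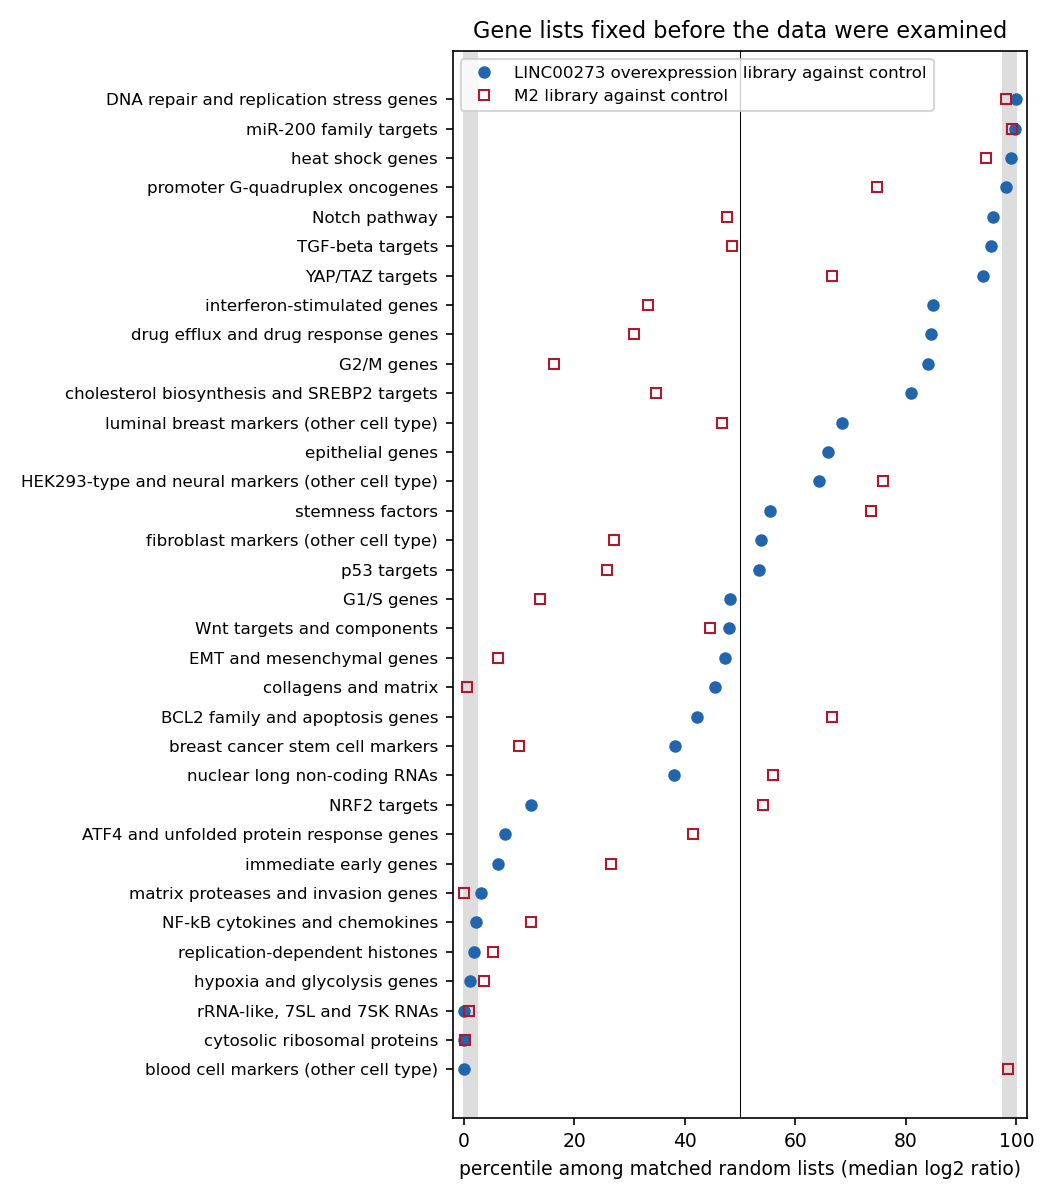
Percentile of each gene list's median log2 ratio to the control among matched random lists (x axis, percent), for the library labelled LINC00273 overexpression (filled circles) and the M2 library (open squares); the grey bands hold the outer 5% of random lists. Blood cell markers lie at percentile 0 in the first library and 98.4 in the second, and miR-200 family targets at 99.8 and 99.3.

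The second comparison asks which transcripts differ after M2. LARP4, an RNA-binding protein that stabilises messages, was 6.64-fold higher than in the control (76 against 328 reads, log2 2.73, 2.21 to 3.28), and TFRC, the transferrin receptor, was 5.31-fold higher (2.41, 2.10 to 2.73). SMC3, a subunit of cohesin, stood at 2.14 (1.94 to 2.34) and the Hippo kinase LATS1 at 2.09 (1.68 to 2.52). EHD2, a protein of caveolae, was 9.23-fold lower (−3.21, −4.30 to −2.29). SPARC, a secreted matrix glycoprotein, was 4.76-fold lower (3272 against 447 reads, −2.25, −2.46 to −2.05), and the syndecan SDC1 (−2.67) and the kinase AKT2 (−2.50, −3.88 to −1.37) were also lower.

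With M2, 661 of 3805 genes were at least 2-fold higher and 338 at least 2-fold lower than in the control. The size rule again ensures that each counting interval lies beyond 0. Also among the 10 highest protein-coding genes were the SUMO protease SENP1 (2.38, 1.66 to 3.16), SP4 (2.34), the nucleolar helicase DDX21 (2.25), KIF21A (2.22), GLCE (2.17) and OTUD4 (2.16). The lowest included TINAGL1 (−2.55), UBTD1 (−2.31), OLFML3 (−2.27), ACAP1 (−2.27) and MAGED2 (−2.19). Of the other genes, the pseudogenes NPM1P37 (1.61) and HSPD1P1 (1.48) and RP11-90H3.1 (1.46) were highest, and CTD-2328D6.1 (−3.44), RPL12P38 (−2.38) and ANXA2P2 (−2.10) lowest. The trend with GC content was steeper here, with a rank correlation of −0.69 and median ratios of 0.91 in the fifth of genes with the lowest GC content and −0.67 in the fifth with the highest. With gene length it was 0.38, and 0.24 given GC content. Centring on GC content left 175 higher and 239 lower genes (42.3% higher, against 66.2%), of which 138 and 112 had passed before. All 20 of the highest and lowest protein-coding genes stayed past 2-fold, LARP4 at 1.79, TFRC at 1.61, EHD2 at −2.49 and SPARC at −2.15, but none of the 3 highest other genes did (NPM1P37 at 0.80, HSPD1P1 at 0.73 and RP11-90H3.1 at 0.82). Scaling to the total count moved the median by 0.26 and gave 969 higher and 166 lower genes (85.4% higher). The split also turned with the read minimum, to 971 higher and 1150 lower genes at 20 reads (45.8%) and 298 and 85 at 500 reads (77.8%).

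Matrix proteases and invasion genes had the lowest median of the lists after M2, −1.55 over 7 members (percentile 0.02). This median is the bound of ADAMTS1 (27 and 0 reads) against 3 fragments and not a measured ratio. With a minimum of 100 reads the median was −0.53 over 4 members (percentile 7.54), and with no minimum −0.34 over 22 (percentile 23.6), both inside the central 95%. At the main minimum 5 were at least 1.5-fold lower and 2 higher. MMP14, a membrane protease that degrades collagen, stood at −2.04 (259 against 41 reads, −2.79 to −1.36) and its partner TIMP2 at −1.87 (−2.30 to −1.47). ADAM10 was higher at 1.64. Collagens and matrix had a median of −0.95 (percentile 0.63) with 12 of 14 lower and 0 higher, among them COL4A2 (−1.99), FBN1 (−1.84) and THBS1 (−1.19, −1.26 to −1.11). Ribosomal proteins (median −0.50, percentile 0.22, 11 of 27 lower, 1 higher) and the 7SL, 7SK and rRNA-like RNAs (−0.71, percentile 1.06, 6 of 10 lower), with RPPH1 at −1.52, were the other low lists. Above the central 95% lay miR-200 family targets (0.66, percentile 99.3, 10 of 20 higher, 1 lower), with SUZ12 at 1.86 and BMI1 at 1.35, and DNA repair genes (0.42, percentile 98.1, 8 of 17 higher, 2 lower). BLM stood at 1.96, ATRX at 1.60, DHX9 at 1.48 and ATR at 1.24. Blood cell markers were higher in all 7 measured members (0.90, percentile 98.4), including LYZ (2.12), HBA2 (0.88) and HBB (0.78, 0.70 to 0.86), and with a minimum of 100 reads the 3 that remained lay at percentile 82.1. With GC centring 2 of these 7 lists stayed outside the central 95%: the proteases, with a median of −1.32, and the blood cell markers.

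EMT and mesenchymal genes had a median of −0.34 after M2 (percentile 6.27, 7 of 14 lower, 4 higher). AXL (−1.62, −2.50 to −0.83) and PRRX1 (−1.19) were lower and CDH2 (1.85) was higher. After GC centring this list lay at −0.60, above 0.04% of random lists. Stemness factors had a median of 0.16 and a mean of −0.16 (percentile 73.8), with BMI1 (1.35) higher and HMGA2 lower (753 against 245 reads, interval −1.30 to −0.70). SOX2 stood at 0.32 (−0.08 to 0.72). Breast cancer stem cell markers had a median of −0.87 over 4 members (percentile 9.95), with CD44 at −0.95 (−1.92 to −0.06) and ITGA6 at 0.71. Drug efflux and drug response genes had −0.23 (percentile 30.9): the topoisomerases TOP2A (1.43, 1.31 to 1.55) and TOP2B (1.35) were higher, and ABCC2 had 28 and 5 reads. Epithelial genes had 2 measured members and no median. Promoter G-quadruplex oncogenes had 0.05 (percentile 74.8), and CCND1 had 44 and 2 reads (−3.84, −9.21 to −1.21). TGF-beta targets had −0.20 (48.6), with TGFB1 lower (−2.21) and SKIL (2.66) and SMAD7 (1.54, 1.26 to 1.83) higher.

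The other lists lay within the central 95% after M2. Heat shock genes had a median of 0.56 (percentile 94.6), with the mitochondrial chaperonin HSPD1 at 1.73 (1.62 to 1.84) and HSP90AA1 at 1.33. Hypoxia and glycolysis genes had −0.52 (3.62), with EGLN3 at −1.70, ENO1 at −1.28 and ALDOA at −1.17, and replication-dependent histones had −0.60 (5.31). G1/S genes stood at −0.48 (13.8) and G2/M genes at −0.52 (16.3, 7 of 16 lower, 3 higher). On the G2/M list the proliferation marker MKI67 had 18 and 2 reads and CDK1 26 and 4. TOP2A, the G2/M gene with the most reads, went the other way with 1814 and 3182. Medians were −0.13 for the Notch pathway (47.7), −0.19 for Wnt targets and components (44.5, FZD1 at −2.05), 0.04 for YAP/TAZ targets (66.6, CRIM1 at 1.75), −0.43 for p53 targets (25.9) and −0.07 for BCL2 family and apoptosis genes (66.6). They were −0.51 for interferon-stimulated genes (33.4), −1.0 for NF-kB cytokines and chemokines (12.2), −0.24 for ATF4 and unfolded protein response genes (41.4, XBP1 at −2.65), −0.40 for cholesterol biosynthesis and SREBP2 targets (34.7, SREBF2 at −1.12), −0.11 for NRF2 targets (54.1, GCLC at 1.14) and −0.24 for immediate early genes (26.7). Nuclear long non-coding RNAs had −0.19 (56.0, OIP5-AS1 at 1.82), luminal breast genes −0.38 (46.7, FOXA1 at −1.64), fibroblast genes −0.64 (27.3) and HEK293-type and neural genes 0.32 (75.8, ENO2 at −1.08).

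**Figure D2:**
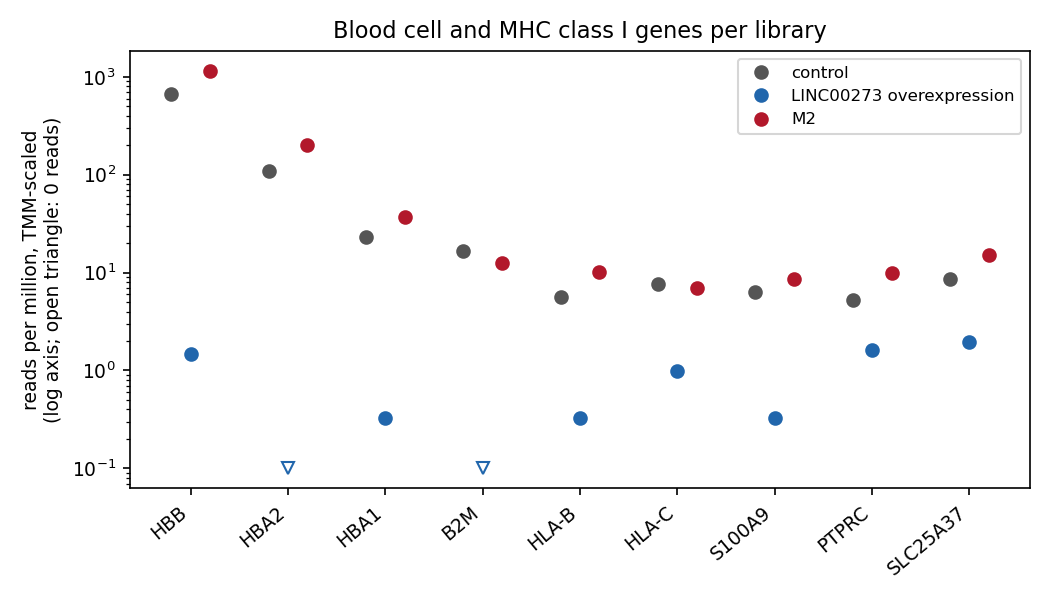
TMM-scaled CPM (log axis) of blood cell and MHC class I genes in each library; an open triangle marks 0 reads. HBB had 4860 reads in the control, 9 in the library labelled LINC00273 overexpression and 5417 in the M2 library.

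Since the labels give the 2 treatments opposite tumour phenotypes, their libraries were also set side by side. Globin genes separated them most: HBB had a log2 ratio of 9.62 (8.34 to 11.36) in M2 against the library labelled LINC00273 overexpression, HBA1 one of 6.84 (4.33 to 12.16), and HBA2 was 206-fold higher at its bound. The transcription factors SP4 (1.91, 1.21 to 2.66) and ARID5B (1.80) and the interleukin receptor subunit IL1RAP (1.72) were also higher with M2. CREB3L1, a membrane-bound transcription factor that activates collagen genes, was lower (181 against 24 reads, −2.53, −3.53 to −1.65), as were EHD2 (−2.27), the phosphatase PTPRU (−2.11), TMEFF2 (−2.10, −2.54 to −1.68) and SPARC (−1.61, −1.83 to −1.40). In all, 56 of 3404 genes were at least 2-fold higher with M2 and 50 lower. The median log2 ratio was 0.29, so the 2-fold bounds were not centred on it. Simulated unchanged libraries put 1.9 genes past 2-fold with counting noise only. They put 119 there with a biological coefficient of variation of 0.2 and 951 with 0.4, and that variation is unknown here. TMEM47 (1.68), THUMPD1 (1.47), TRIM23 (1.47) and FNTA (1.41) completed the 10 highest protein-coding genes, and CHSY1 (−1.77), FLRT2 (−1.67), MID1 (−1.66), FADS3 (−1.62) and TNRC18 (−1.57) the 10 lowest. Among other genes, RP1-159A19.3 (1.44), NPM1P37 (1.41) and RPS3AP44 (1.23) were higher, and CTD-2328D6.1 (−1.55), KCNQ1OT1 (−1.37) and HSP90B2P (−0.97) lower. Scaling to the total count moved the median by −0.26 and gave 17 higher and 113 lower genes (13.1% higher, against 52.8%). GC centring gave 14 and 96 (12.7%), with 8 of the 10 highest protein-coding genes and 1 of the 3 highest other genes still past 2-fold. FNTA fell to 0.93, and HBA2 had no centred value.

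The ratios to the control were positively correlated between both libraries. Of 3772 genes tested in both comparisons, 153 were at least 2-fold higher in both and 98 lower in both, where independent lists would share 29 and 22.8. 0 genes were 2-fold higher in one and 2-fold lower in the other, where independent lists would share 15.4 and 42.8. GLCE, LARP4 and TFRC were among those higher in both, and TINAGL1 among those lower in both. Across 3770 genes the Pearson correlation of the log2 ratios was 0.803 and the Spearman correlation 0.832, genes not being independent replicates. Both comparisons use the same control library, which alone makes such values positive and the lists not independent. Simulated unchanged libraries against that control gave a correlation of 0.429 with counting noise only and 0.464, 0.493 and 0.499 with an added biological coefficient of variation of 0.1, 0.2 and 0.4. In the order of the comparisons described, these unchanged libraries put 1.65, 3.05 and 1.9 genes past 2-fold with counting noise only, 128, 128 and 119 at a variation of 0.2, and 1022, 968 and 951 at 0.4, and the variation between cultures is unknown here. The observed covariance was 0.459, and the simulated covariances were 0.0156, 0.0368, 0.104 and 0.388. Splitting the control reads at random between the comparisons gave a correlation of 0.753, which separates counting noise but not the sample itself. The simulations gave each library equal noise, and a control that deviates more than the other libraries would raise the correlation further. The SD of the log2 ratios was 0.69 (labelled LINC00273 overexpression) and 0.85 (M2) against the control, and 0.49 between these libraries. Part or all of the excess may therefore come from the shared control. After GC centring the correlation was 0.686 and the covariance 0.235.

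**Figure D3:**
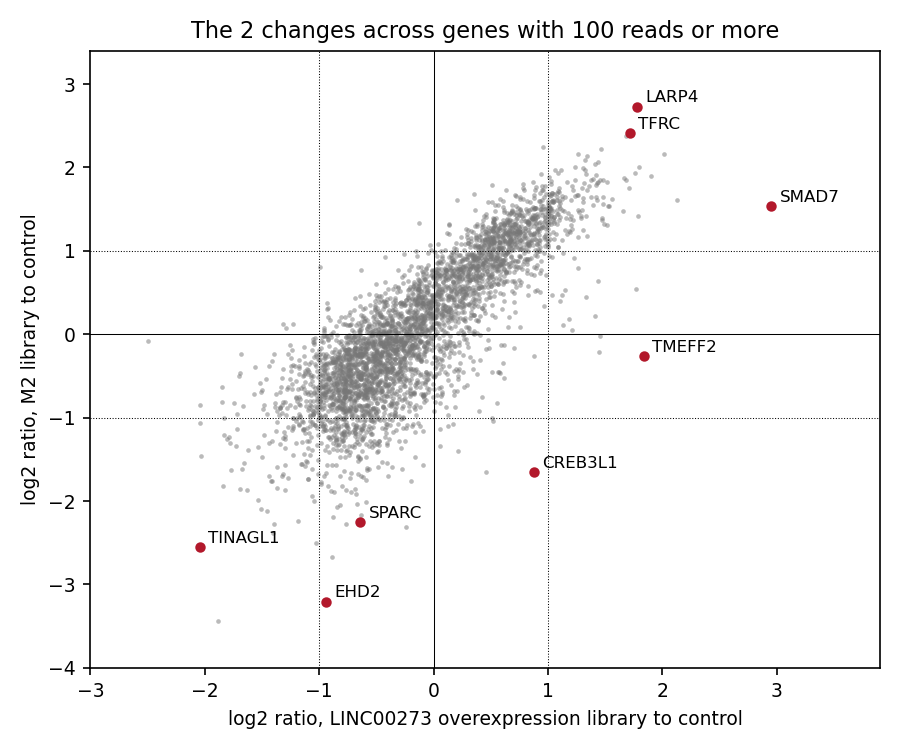
Log2 ratio to the control of each gene with at least 100 reads, in the library labelled LINC00273 overexpression (x axis) and in the M2 library (y axis); dotted lines mark 2-fold. The points rise together (Pearson correlation 0.803), SMAD7 and TMEFF2 lie to the right of the trend, HBB and HBA1 lie beyond the left edge, and HBA2 and B2M, with 0 reads in one library, are not drawn.

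The authors also deposited lists of up- and down-regulated genes. The authors' deposited table held 479 up and 330 down genes for the library labelled LINC00273 overexpression and 294 up and 376 down genes for M2. The bounds of these lists in the authors' deposited table matched the mean plus and minus 2 SD of the log2 ratio over 15948 and 14195 genes above 0 in both libraries, at 2.17 and −1.86 and at 2.14 and −2.06. Recomputed in this way the counts were 479 and 371, and 294 and 376. The 41 further genes all share the log2 ratio of −1.86 next to the bound. Low counts dominated these lists: the median number of reads per gene over both libraries was 12 and 16 (up and down, LINC00273) and 10 and 20 (M2), and the counting interval lay beyond 0 for 25.7%, 31.5%, 29.9% and 37.8% of the listed genes. Simulated unchanged libraries put 238 genes above and 253 below the same bounds for the first comparison, and 322 and 118 for M2. Of 13207 genes in both of the authors' tables, 113 were on both up lists and 35 on both down lists, where independent lists would share 6.87 and 7.37. Part or all of this overlap may come from the shared control.

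In the authors' deposited table of terms, genes down in the library labelled LINC00273 overexpression were enriched for the MHC class I protein complex (25.65-fold, FDR 0.0446), interferon-gamma-mediated signaling (8.55-fold, FDR 0.0138) and neutrophil degranulation (3.35-fold, FDR 0.0385). The down list held HLA-B, HLA-C and HLA-E, 3 of 7 MHC class I genes, and the blood cell genes ALAS2, S100A8, S100A9, SLC25A37 and SRGN. For genes up in that library the authors' deposited table listed 3 terms: the intrinsic component (1.91-fold, FDR 0.000486) and the integral component of the plasma membrane (1.89-fold, FDR 0.000865) and vitamin transmembrane transporter activity (11.08-fold, FDR 0.0431). For genes down with M2 the authors' deposited table listed 25 terms, among them the synaptic membrane (3.3-fold, FDR 0.00354), the lysosome (2.43-fold, FDR 0.0144) and small molecule metabolic process (1.95-fold, FDR 0.0199).

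**Figure D4:**
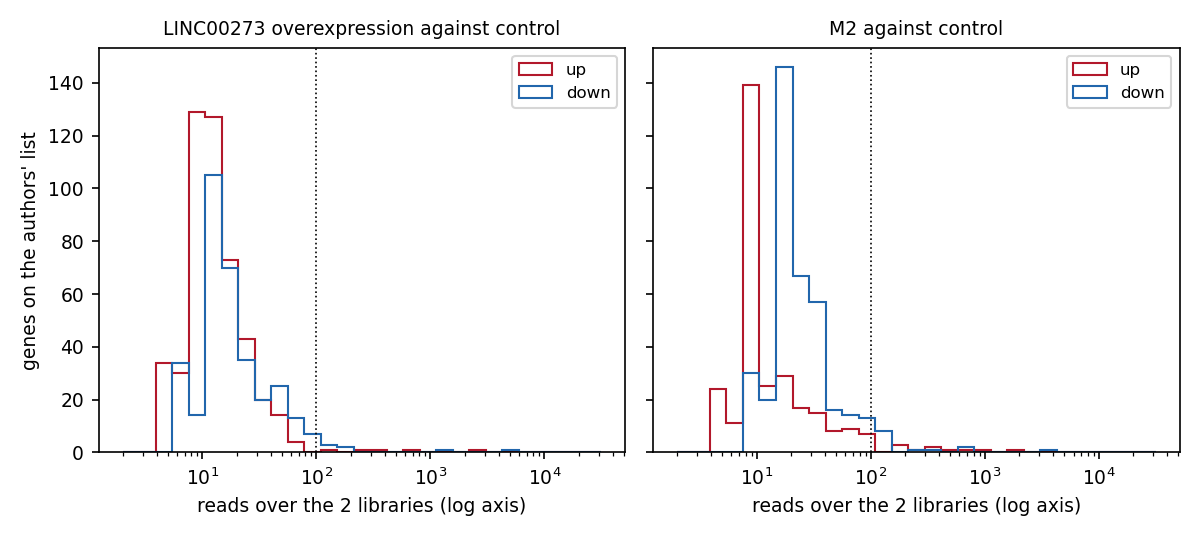
Number of genes on the authors' up and down lists (y axis) by reads over both libraries (x axis, log scale), for each comparison with the control; the dotted line marks 100 reads. Of the 479 genes up in the library labelled LINC00273 overexpression, 393 had at most 20 reads.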

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

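The tests in this part were chosen after the result was seen. Of 3875 genes with at least 100 reads in a library, 6 moved at least 1.5-fold in opposite directions in the library labelled LINC00273 overexpression and in the M2 library, each with its counting interval beyond 0, and with 1 library per group the difference was not tested. ARID5B had log2 ratios to the control of −0.99 and 0.81, CREB3L1 of 0.87 and −1.65, and FNTA of −0.64 and 0.78. FNTA moved less than 1.5-fold in one library with the deposited size factors (−0.56), scaling to the total count (−0.12) and GC centring (−0.06), as did ARID5B with scaling to the total count (−0.47). With DESeq2 size factors FNTA still moved 1.5-fold in opposite directions (−0.59 and 0.83), but a counting interval reached 0. CREB3L1 and the globin genes kept their opposite moves under each of these settings. Scaling to the total count gave 13 such genes in all and GC centring 16. Of the globin genes, HBB stood at −8.85 and 0.78, HBA1 at −6.16 and 0.68, and HBA2 had 0 reads in the library labelled LINC00273 overexpression and a log2 ratio of 0.88 in the M2 library.

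The globin difference went with other blood genes. A red cell, granulocyte and lymphocyte list without the globins was compared with the mean of the control and M2 libraries, with 5 reads added. Of its 33 genes 15 were measured, here by at least 20 reads over the control and M2 libraries alone. Their median log2 ratio to that mean was −1.49 in the library labelled LINC00273 overexpression, at percentile 0 of matched random lists. 11 of the 15 had at most 0.5 of the level in both other libraries, as did 3.51% of 7988 genes. S100A9 had 46, 2 and 40 reads and ALAS2 60, 5 and 20 in the control, that library and the M2 library, whereas IL7R had 11, 16 and 18. Yield that depends on base composition is argued against as the whole cause, since HBB stood at −8.26 after GC centring. A candidate explanation is blood RNA in the control and M2 libraries that the other library lacks, a hypothesis formed on the same data, and the culture labels name no source of blood. An effect of LINC00273 itself cannot be told apart from a difference between libraries, because LINC00273 had 0 reads (up to 1.17 CPM, if its reads could be counted) and each label has 1 library.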

How the results depend on the processing

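The size factors of the deposited values and GC centring were chosen after the result was seen; the other alternatives were planned. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. No named gene past 2-fold and no list outside the central 95% changed direction under the alternatives that gave a value, but several lists moved inside the central 95%. For the library labelled LINC00273 overexpression, 9 of 10 lists stayed outside with DESeq2 size factors and with scaling to the total count (without the NF-kB list), 7 of the 9 with a value at 100 reads (without the promoter G-quadruplex oncogenes and the histones), 8 of 10 with no minimum (without the heat shock and hypoxia lists), 8 of 9 among protein-coding random lists (without the promoter G-quadruplex oncogenes, percentile 97.4) and 7 of 10 with GC centring. For M2, 4 of the 6 with a value stayed outside at 100 reads (without the proteases and the blood cell markers), 6 of 7 with no minimum (without the proteases) and 2 of 7 with GC centring. Other lists moved outside. For the library labelled LINC00273 overexpression these were the TGF-beta targets (percentile 100, median 0.90), YAP/TAZ targets (99.3) and immediate early genes (1.67) at 100 reads, the proteases with scaling to the total count (2.33), the drug genes with no minimum (98.9), and with GC centring the Notch pathway (99.7), the TGF-beta (99.97) and YAP/TAZ (99.7) targets and nuclear long non-coding RNAs (1.25). For M2 they were the histones at 100 reads (2.39) and with no minimum (1.69), heat shock genes (98.3) and metallothioneins (97.8) with no minimum, and with GC centring stemness factors (98.9), TGF-beta targets (98.4), heat shock genes (98.6), EMT genes (0.04) and nuclear long non-coding RNAs (2.26). The cause was not tested for the scalings and random lists. Values stayed within counting error, or counts within 1.5 times, in 2071 of 2269 runs for named genes, 387 of 451 for list medians and 28 of 60 for counts of genes. The 387 include 63 runs against protein-coding random lists, a setting that leaves the members' ratios unchanged. With scaling to the total count 29 list medians moved and 38 did not, and with GC centring 18 and 49. Of the named-gene values 81 moved and 375 did not with scaling to the total count, and 111 and 334 with GC centring. Lists with fewer than 3 members at a higher minimum, and GC-centred values of genes with 0 reads in a library, have no value. For the library labelled LINC00273 overexpression against the control, higher and lower genes numbered 823 and 37 with scaling to the total count, for which the cause was not tested beyond the median shift. They numbered 608 and 706 at 20 reads, 73 and 77 at 500 reads, 6087 and 4947 with no minimum, and 6 and 9 at 4-fold, by the construction of these settings, and GC centring left 138 and 134. For M2 against the control they numbered 969 and 166 (total count), 971 and 1150 (20 reads), 298 and 85 (500 reads), 4370 and 7125 (no minimum), 16 and 19 (4-fold) and 175 and 239 (GC centring). For M2 against the library labelled LINC00273 overexpression they numbered 17 and 113 (total count), 287 and 729 (20 reads), 11 and 10 (500 reads), 3388 and 7513 (no minimum), 3 and 4 (4-fold) and 14 and 96 (GC centring). The correlation of both changes was 0.637 at 20 reads, 0.837 at 500 reads, 0.753 with the control reads split and 0.686 with GC centring. Depth limits PROM1 and ALDH1A1, which had too few reads for a difference to be detectable, and why LINC00273 had 0 reads was not tested.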

Other observations

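The tests in this part were chosen after the result was seen. MHC class I genes, which present peptides to T cells, were examined after B2M was seen at 0 in the library labelled LINC00273 overexpression. HLA-B had 41, 2 and 47 reads, HLA-C 55, 6 and 33, HLA-E 53, 5 and 44 and HLA-G 25, 12 and 0 in the control, that library and the M2 library. Blood cell genes were low in the same library. The list without globins had a median log2 ratio of −1.49 to the mean of the control and M2 libraries, and PTPRC had 38, 10 and 46 reads. The nuclear RNA NEAT1, the scaffold of paraspeckles, had 36, 2 and 24 reads, and the small Cajal body RNA SCARNA2 had 42, 6 and 40.

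In both libraries GC-poor genes were higher and GC-rich genes lower than in the control, with rank correlations of −0.60 and −0.69. A peculiarity of the control library is argued against only as the sole source of this trend. The M2 library set against the library labelled LINC00273 overexpression, without the control, still had a rank correlation of −0.39. The control stays open as the main source. Without it, median log2 ratios were 0.47 for genes of lowest GC content and 0.006 for those of highest, grouped as in the Results. Against the control they were 0.45 and −0.62 (labelled LINC00273 overexpression) and 0.91 and −0.67 (M2). Yield that depends on base composition and differs between the libraries stays open: within the gene lists 42 of 48 rank correlations with GC content (87.5%) were negative, but genes that carry the overall trend would give this whatever its cause. A response shared by LINC00273 overexpression and M2 stays open as well, since library and treatment cannot be told apart with 1 library per group. The correlation of both changes was 0.686 after GC centring, but the shared control alone makes it positive. Simulated unchanged libraries, without centring and with equal noise in each library, gave 0.429 to 0.499. The centred covariance was 0.235, and unchanged libraries with a biological coefficient of variation of 0.4 gave 0.388.

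Ribosomal protein genes, whose products are needed in equal numbers, had 0 to 59459 control reads over 76 genes: RPL15 had 59459 and RPLP0 42633, while RPS2 had 22 and RPS6 32. The same order held in the other libraries (rank correlations 0.989 and 0.988). Epithelial genes had a median of 4 control reads where VIM had 11763, and whether this is usual for MDA-MB-231 cells was not examined. Loss of reads to near-identical copies stays open. The 19 genes with at most 3 pseudogenes were about as uneven as the other 57 (ratio of SDs of log10 reads 0.882, interval 0.653 to 1.09). This comparison cannot decide, since only RPL28 of the 19 had 0 pseudogenes and a few copies may be enough to take reads. Pseudogenes were also counted by name and not by sequence identity. RNA of another mammal aligned to the human genome could leave few reads on mitochondrially encoded genes, which had 9 over the 3 libraries, but a filter before counting could do the same and these cannot be told apart here, no other genome having been compared. No biological explanation was tested.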
